A study of Hansenia forbesii with 12 samples.

How the data were processed

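RNA was extracted from roots and canopies, and libraries of messenger RNA broken to 300 bp were sequenced as paired reads of 150 bp on an Illumina HiSeq instrument, per the labels' protocols. The authors deposited 1 table of whole-number read counts per gene with 12 columns, each of which matched the title of 1 sample. The gene identifiers have the form that the Trinity assembler gives to genes of a de novo assembly, per the file headers and row names, and the quantification tool RSEM is named in the submitters' processing notes. The versions, the aligner, the filters and the role of each tool are not given in the sources used here. The values were not normalized, and the column totals of the deposited counts ranged from 6895655 to 10556974. A de novo assembly splits and merges genes, so the number of genes with a count includes fragments and near-identical copies. No genome or gene annotation was used, and the file does not pair identifiers with gene names, so coordinates, gene names and the 12 gene lists fixed beforehand could not be used.

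The table holds 65535 genes, which is the number of data rows that an older spreadsheet format can hold, and it may hold part of a larger table. The totals above are therefore totals of the listed rows, not the sequencing depth, which is unknown. Whether the listed rows of each library belong to the same set of genes is unknown too, and all measures within a library depend on which genes are listed.

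Samples were grouped by the code in their titles. The fixed design was an edgeR quasi-likelihood test (robust dispersion, TMM factors, filterByExpr) over all 12 libraries with a contrast for each of the 4 comparisons and 1 for the interaction, and a Benjamini-Hochberg threshold of 0.05. It was written, with its alternatives, before the data were examined. The counts were then checked for row order by Spearman correlations between all pairs of libraries, by the overlap of the 100 most abundant genes, by all cyclic shifts and reversals of whole columns, and by the relation of counts to the component number in the identifiers. The check was tested on simulated data: a table of 65535 aligned genes with the first vegetative root library as its means and a dispersion of 0.1 gave correlations of 0.975 to 0.984 between libraries, and the same table with 11 columns shuffled gave an absolute correlation of at most 0.010. The edgeR test was run on a simulated canopy stage comparison of the same kind with 200 changed genes in a fit of 12792 genes. It recovered 8% of 50 genes changed 2-fold, 92% of 50 changed 4-fold and 100% of 50 changed 8-fold and of 50 changed 16-fold, and it called 5 unchanged genes. The changed genes were drawn from those with at least 50 counts in the library that gave the means, so recovery at lower counts was not measured. After the columns were shuffled, the filter kept 22402 genes and the test called 0 of them.

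Because the rows were found not to match, measures within each library were added after the data had been seen. These were the number of genes above a count, the number expected at a common depth of 6895655 counts (the exact hypergeometric expectation), the number in classes of abundance and the effective number of genes. The share of counts in the 10 most abundant genes had been planned. Groups of 3 libraries were compared by exact two-sided permutation tests over 20 labelings, whose smallest p is 0.1. Part and stage were also tested over all 12 libraries by permuting labels within the other factor, with 400 labelings and a smallest p of 0.005. The interaction was tested by permuting the residuals of the model without it 100000 times. Each share of the 65535 listed genes with a count in a single library has a 95% Wilson interval narrower than 1 percentage point, from 24.6 to 25.3% in the second reproductive root library and from 54.3 to 55.1% in the third reproductive canopy library. Such intervals treat the listed genes as independent draws, which they are not, and do not cover the spread between libraries.

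The labels do not say that a replicate number marks a shared plant or batch, and the libraries were treated as unpaired. A row-by-row check of pairing gave correlations between -0.010 and 0.011 over 18 pairs of same-numbered libraries, but it could not show pairing, because the rows do not match. Replicate 3 had the highest total count in all 4 groups, so pairing is not excluded (1 number would be highest in all 4 by chance with a probability of 0.037). The labels give no sequencing batch. The rule for named genes asked for called genes, and since edgeR called none, no gene is named. RLE factors could not be computed, because 0 genes have a count in all 12 libraries, and size factors from the positive counts were used in their place, in DESeq2 too. Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.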

Results

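Transcript abundance was measured by RNA sequencing in roots and canopies of Hansenia forbesii, a perennial medicinal herb of the carrot family that is also known as Notopterygium franchetii. The plants were 2 years old, and the study was concerned with the accumulation of coumarins, a class of phenylpropanoid-derived metabolites, in the 2 plant parts at different stages of growth. The 12 libraries form 4 groups of 3, which are the canopy and the root during vegetative growth and the same parts during reproductive growth. The group codes combine a letter for the stage with a letter for the part, and this reading was taken from the series' design and not from a written key. The labels do not say whether the 3 libraries of a group came from separate plants, so every p-value below measures only the spread between these libraries.

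The count table listed 65535 genes of a de novo assembly. The total counts per library ranged from 6895655 in the second reproductive canopy library to 10556974 in the third reproductive root library. The mean was 8198433 ± 626724 counts (SD, n = 3) in the vegetative canopy and 7723118 ± 947169 (SD, n = 3) in the reproductive canopy. It was 8289311 ± 377944 (SD, n = 3) in the vegetative root and 9780781 ± 848087 (SD, n = 3) in the reproductive root.

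A row of this table did not hold the same gene in every library. Across the 65535 rows, the Spearman correlation of counts lay between -0.0097 and 0.0096 for the 66 pairs of libraries, and between -0.0072 and 0.0096 for the 12 pairs of replicates. When every column was shuffled at random, the largest absolute correlation of the 66 pairs was between 0.0071 and 0.015 over 20 shuffles. The 100 most abundant genes of a library shared 0 rows with those of its replicates in all 12 replicate pairs. The number of libraries in which a row had a count also followed the numbers that 12 unrelated columns would give. For example, 15996 rows had a count in 4 libraries where 16057 were calculated, and 0 rows had a count in all 12.

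The gene identifiers fitted 1 library. In the first vegetative root library, counts fell with the component number in the assembly's identifiers, with a Spearman correlation of -0.52 across genes. In that library 65.0% of genes with the lowest 25% of component numbers had a count, against 7.84% with the highest 25%. Genes of the same component also had related counts there, with a Spearman correlation of 0.49 over 1759 pairs. In the 11 other libraries the correlation with the component number lay between -0.0095 and 0.0074, and that between genes of 1 component lay between -0.033 and 0.040. Genes are not independent replicates, and these correlations describe the table only. For these reasons no gene is named here as higher or lower in a plant part or at a stage, and neither the coumarin pathway nor any other gene group was compared. The comparisons below use the list of counts within each library, which does not depend on the order of the rows. It is unknown whether the rows listed for each library cover the same genes, and every measure below depends on which rows are listed.

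**Figure D1:**
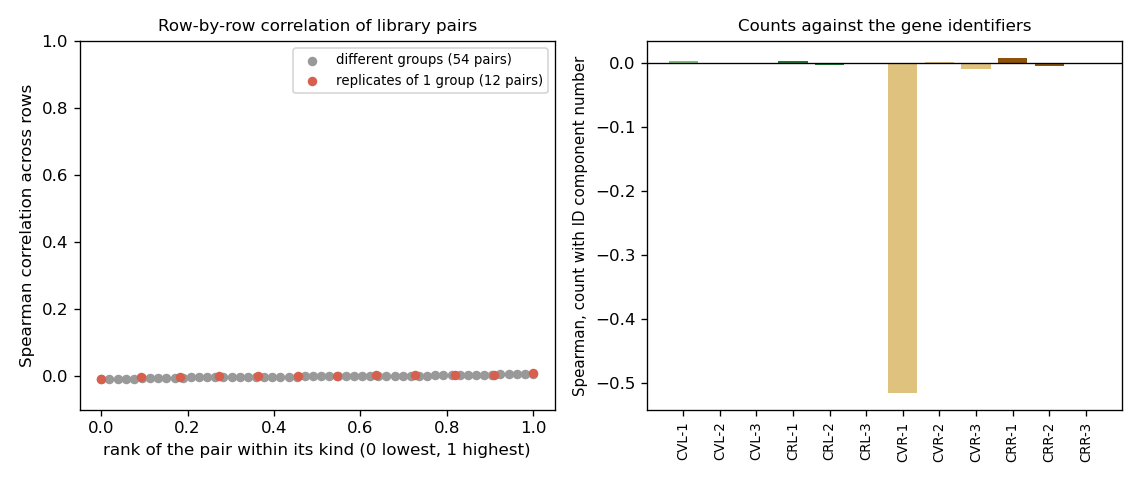
The left panel plots the Spearman correlation across the 65535 rows for each pair of libraries, ordered from lowest to highest within each kind of pair, and all 66 pairs lie between -0.0097 and 0.0096. The right panel plots, for each library, the Spearman correlation of its counts with the component number of the gene identifiers, which is -0.52 in the first vegetative root library (CVR-1) and between -0.0095 and 0.0074 in the others.

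The first comparison asked how the canopy transcriptome differed between the growth periods. The reproductive canopy had the largest number of genes with a count among the 4 groups. A count was found for 34317 ± 1640.0 genes (SD, n = 3) in the reproductive canopy and for 20807 ± 606 genes (SD, n = 3) in the vegetative canopy, a ratio of 1.65. Most of the net difference lay in the classes of low abundance, and single genes could not be followed between libraries. Genes with 1 to 9 counts numbered 14866 ± 1152 in the reproductive and 7422 ± 683 in the vegetative canopy, and genes with 10 to 49 counts numbered 12154 ± 865 and 6486 ± 361. Genes with at least 100 counts numbered 5525 ± 233 and 5333 ± 164, a difference within the range of the replicates (exact permutation test, two-sided, p = 0.5). The counts of the reproductive canopy were also less concentrated in the most abundant genes. Its 10 most abundant genes held 7.36 ± 0.773% of the counts, against 13.8 ± 3.40% in the vegetative canopy. Its effective number of genes (the exponential of the Shannon entropy of the counts) was 2767 ± 181 against 1685 ± 288. This ratio of 1.64 was near the 1.65 for genes with a count, so the effective number is not a separate sign of evenness. For the number of genes with a count, the top-10 share and the effective number, all 3 libraries of one stage lay apart from all 3 of the other (exact permutation test, two-sided, p = 0.1 for each, the smallest value that 3 libraries against 3 allow). At a common depth of 6895655 counts the genes with a count numbered 34203 ± 1569 and 20657 ± 653.

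In the root, the same comparison of growth periods gave small differences in the number of genes and a larger one in how the counts were distributed. A count was found for 16648 ± 317 genes (SD, n = 3) in the reproductive root and 17882 ± 683 genes (SD, n = 3) in the vegetative root, a ratio of 0.931. Genes with 1 to 9 counts numbered 4533 ± 369 in the reproductive and 6508 ± 481 in the vegetative root, while genes with at least 10 counts numbered 12115 ± 411 and 11374 ± 212. The most abundant gene of each library held 7.60 ± 2.90% of the counts in the reproductive root and 1.57 ± 0.136% in the vegetative root. The 10 most abundant genes held 18.0 ± 4.20% and 10.8 ± 0.110%. The effective number of genes was 1219 ± 242 in the reproductive and 1708 ± 97 in the vegetative root. The 3 libraries of each stage did not overlap in any of these 6 measures (exact permutation test, two-sided, p = 0.1 for each, the smallest value possible). Without the 10 most abundant genes of each library the effective numbers were 2162 ± 5.58 and 2176 ± 135 and overlapped (exact permutation test, two-sided, p = 0.7), so this difference lay in those 10 genes. Total counts did not overlap either and were 1.18 times as high in the reproductive root (exact permutation test, two-sided, p = 0.1). With a minimum scaled to the total, 1 CPM, genes numbered 12239 ± 94.7 in the reproductive and 12045 ± 667 in the vegetative root, and the libraries overlapped (exact permutation test, two-sided, p = 0.7).

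**Figure D2:**
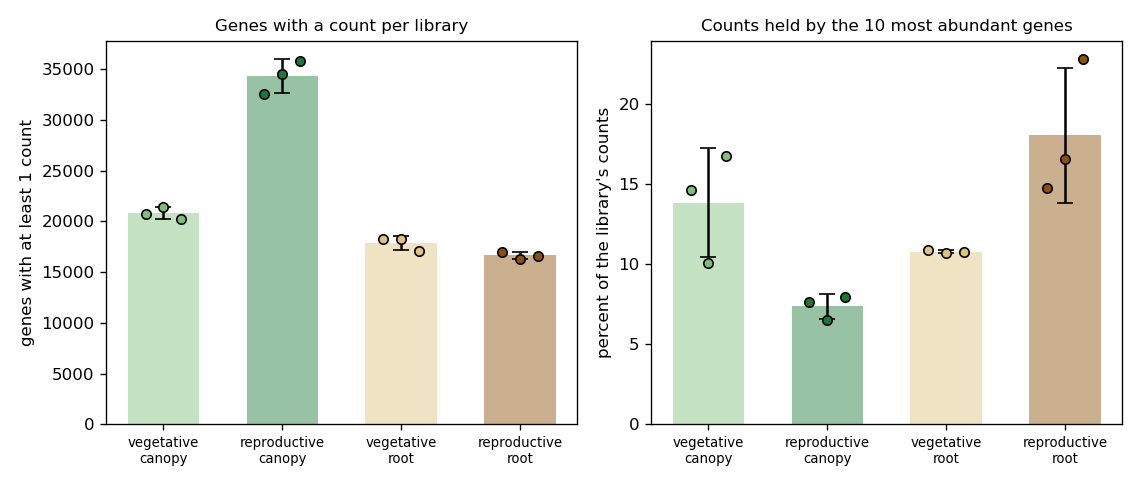
Bars give the mean of 3 libraries per group, error bars the SD and points the single libraries, for the number of genes with at least 1 count (left) and for the percent of a library's counts held by its 10 most abundant genes (right). The reproductive canopy stands at 34317 genes against 16648 to 20807 in the other groups, and it has the lowest top-10 share, 7.36%, while the reproductive root has the highest, 18.0%.

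The next comparisons asked how root and canopy differed within each growth period. During vegetative growth fewer genes had a count in the root than in the canopy, 17882 ± 683 against 20807 ± 606 genes, a ratio of 0.859 (exact permutation test, two-sided, p = 0.1). The root had more genes at the top of the range, with 120 ± 2.65 genes at 10000 counts or more against 94.3 ± 0.577 in the canopy (exact permutation test, two-sided, p = 0.1). The top-10 share was 10.8 ± 0.110% in the root and 13.8 ± 3.40% in the canopy, and the libraries overlapped (exact permutation test, two-sided, p = 0.4). The difference of -3.03 percentage points was -1.56 without the third vegetative canopy library (exact permutation test, p = 0.6) and -4.89 without the second (exact permutation test, p = 0.1). The effective numbers of genes, 1708 ± 97 and 1685 ± 288, overlapped as well (exact permutation test, two-sided, p = 0.9). This difference of 22.8 ranged from -85.6 to 186 when 1 library was left out. Without the 10 most abundant genes of each library the numbers were 2176 ± 135 in the root and 2507 ± 67.0 in the canopy and did not overlap (exact permutation test, two-sided, p = 0.1).

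During reproductive growth the contrast between the plant parts was wider. The root had 0.485 times as many genes with a count as the canopy, 16648 ± 317 against 34317 ± 1640.0, and 140.0 ± 15.7 against 82.7 ± 11.0 genes at 10000 counts or more. The 10 most abundant genes held 18.0 ± 4.20% of the counts in the root and 7.36 ± 0.773% in the canopy, a ratio of 2.45. The 50% of counts in the most abundant genes came from 222 ± 41.2 genes in the root and from 467 ± 38.1 genes in the canopy. The libraries of the parts did not overlap in any of these measures (exact permutation test, two-sided, p = 0.1 for each, n = 3 per part). Total counts were 1.27 times as high in the root.

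Over both growth periods, the number of genes with a count in the root minus that in the canopy averaged -10297 (exact permutation test within stages, two-sided, p = 0.005, the smallest value possible, adjusted p = 0.014). With a minimum of 50 counts per gene the difference was -722 (p = 0.005 and adjusted p = 0.014 by the same permutation test). Over both parts, reproductive libraries had 6138 more genes with a count (exact permutation test within parts, two-sided, p = 0.1, adjusted p = 0.14). This test could not decide on a stage difference, because the changes were 13510 in the canopy and -1235 in the root. The opposite and much smaller root change could not bring p under 0.1, the smallest value for the canopy alone. With a minimum of 50 counts the changes were of the same sign, 398 in the canopy and 218 in the root. Reproductive libraries then had 308 more genes (exact permutation test within parts, two-sided, p = 0.015, adjusted p = 0.034). The stage change differed between the parts. The number of genes with a count changed by 13510 in the canopy and by -1235 in the root, a difference of -14744 (permutation test of the interaction, two-sided, p = 0.0024, adjusted p = 0.014). The top-10 share changed by -6.45 percentage points in the canopy and by 7.24 in the root (permutation test of the interaction, p = 0.0053, adjusted p = 0.014). The effective number of genes changed by 1081 in the canopy and by -489 in the root (permutation test of the interaction, p = 0.0024, adjusted p = 0.014). Without the 10 most abundant genes it changed by 776 in the canopy and by -13.9 in the root, and the difference between the changes went from -1571 to -789.6 (permutation test of the interaction, p = 0.0024). This p recurs for measures of unlike size, so an equal p does not mean equally strong evidence. For genes with at least 50 counts the stage changes, 398 in the canopy and 218 in the root, did not differ past the threshold (permutation test of the interaction, p = 0.54, adjusted p = 0.57). Adjusted values are Benjamini-Hochberg values over 18 tests, which are the part, stage and interaction tests of 6 measures.

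**Figure D3:**
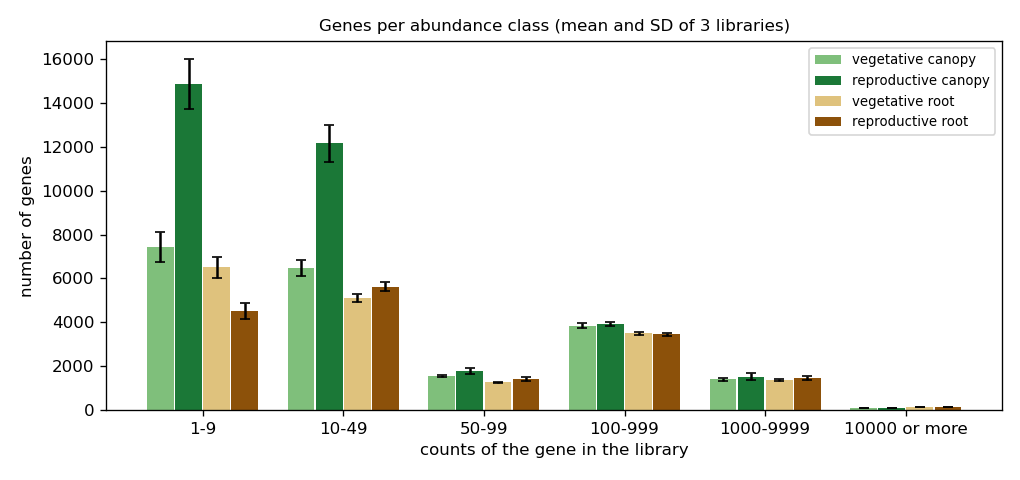
Bars give the mean number of genes per library in 6 classes of the gene's count, with the SD of 3 libraries as error bars, for the 4 groups. The reproductive canopy has 14866 genes with 1 to 9 counts and 12154 with 10 to 49 counts. Summed over the classes from 100 counts up, which no single bar shows, the numbers are 5525 for the reproductive canopy, 5333 for the vegetative canopy, 5059.7 for the reproductive root and 4998 for the vegetative root. At 10000 counts or more the reproductive canopy has 82.7 genes.

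The gene-by-gene tests planned for the 4 comparisons and the interaction were run on the table as deposited. The quasi-likelihood test of edgeR called 0 of 31969 rows at a Benjamini-Hochberg adjusted p of 0.05 in each of them. The rows with an unadjusted p under 0.05 numbered 3132 for the canopy stages, 5136 for the root stages, 4542 for the parts in vegetative growth, 4695 for the parts in reproductive growth and 5507 for the interaction. The common dispersion was 9.54, against 0.10 in a simulated table of aligned rows made with a dispersion of 0.1. DESeq2 called 1661, 3153, 2696, 2418 and 3783 rows in the same order. After each column had been put in a new random order DESeq2 called 1619, 3169, 2763, 2472 and 3655 rows. Since rows do not match genes across libraries, neither the calls nor their absence describe the plants. Because edgeR called 0 rows in each contrast, the overlap of its calls was fixed at 0 beforehand. This holds for the stage changes of root and canopy and for the part differences of the stages. The rows with at least 1 CPM in all 3 libraries of a part and no more than 3 counts over the 3 libraries of the other part numbered 178 for the vegetative root, 307 for the vegetative canopy, 63 for the reproductive root and 1421 for the reproductive canopy, where unrelated columns would give 151, 321, 63.1 and 1401.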

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

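All tests of explanations in this part were chosen after the results had been seen, and the measures other than the top-10 share were added then too. The change from vegetative to reproductive growth differed between root and canopy in 4 measures. The difference, root change minus canopy change, was -14744 for the number of genes with a count, -14815 for the same number at a common depth, 13.7 percentage points for the share of counts in the 10 most abundant genes and -1571 for the effective number of genes. Each was past the threshold in a permutation test of the interaction, with an adjusted p of 0.014.

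For the number of genes with a count, most of this difference is the 13510 by which the number in the reproductive canopy exceeded that in the vegetative canopy. The tests below concern this net excess only. The top-10 share changed by 7.24 percentage points in the root and -6.45 in the canopy, and the cause of neither change was tested. Library depth is argued against as the whole cause. The true depth is unknown, but to reach the vegetative canopy's number of genes with a count the reproductive canopy libraries had to be thinned 12.4- to 16.4-fold, and this left 1199 ± 62.4 genes with at least 100 counts where the vegetative canopy had 5333 ± 164. Counts taken up by a few genes are argued against as well, since the counts outside the 50 most abundant genes were only 1.11 times as large a share in the reproductive canopy, against the 12.4-fold needed. Of this net excess, 97.1% lay in the classes of 1 to 49 counts, a difference of class sizes that follows no single gene. It could come from low-level RNA from further tissues (reproductive organs, for example) or from other organisms in the canopy samples. It could equally come from a wider low-level expression of the plant's own genes at this stage. Without gene names these cannot be told apart. Gene names alone would not settle the cause, since the rows listed for each library may cover different genes. The labels give no batch, so a technical difference shared by the libraries of a group stays open too. A biological effect of the stage remains untested as a cause.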

How the results depend on the processing

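Of these alternatives, those for the counts of genes and the effective number were chosen after seeing the data, as were the size factors from positive counts and the new shuffle. The edgeR and limma-voom fits called 0 rows in all 99 fits over the 5 contrasts, the replicate block and the fits that leave out 1 library included (range 0 to 0), with a lowest adjusted p of 0.25. With the replicate block the unadjusted p was under 0.05 for 528, 361, 358, 924 and 2110 rows (canopy stages, root stages, parts in vegetative growth, parts in reproductive growth, interaction). The block did not change a call. DESeq2 called 1661, 3153, 2696, 2418 and 3783 rows in that order, and 1619, 3169, 2763, 2472 and 3655 after a new shuffle of every column. Its calls for the stages of root and canopy shared 296 rows of the same direction and 288 of the opposite, and those for the parts at the stages shared 381 and 289. The number expected by chance was not calculated. Since rows do not match genes across libraries, these shared rows do not describe the plants. At 5 CPM the rows present in 1 part only were 31 for the vegetative root, 38 for the vegetative canopy, 12 for the reproductive root and 41 for the reproductive canopy. RLE factors were not run.

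The stage difference of the root in genes with a count turned from -1235 to 741 at 10 counts, 218 at 50 counts and 194 at 1 CPM (overlapping libraries in the last 2), and the genes with 1 to 9 counts were those that were fewer. The stage difference over both parts passed the threshold at 10 counts (3403), 50 counts (308) and 1 CPM (4673), and the interaction lost it at 50 counts (-179). The effective number of genes in the vegetative root minus the canopy, 22.8, was -330.3 without the 10 most abundant genes and ranged from -85.6 to 186 when 1 library was left out, turning sign without canopy replicate 1, canopy replicate 3 or root replicate 2. Over both stages the part difference in effective number, -763, passed the threshold without the 10 most abundant genes (-725), and ranged from -817 to -681 with 1 library left out, passing it without vegetative canopy replicate 1 (-790.2, p = 0.045) or 3 (-817, p = 0.04); alternatives are judged on the unadjusted permutation p, which was 0.06 in the main test. The cause was not tested for the effective number. The other 176 alternatives kept their direction and their side of the threshold, which no test of 3 libraries against 3 could pass, but 16 of them moved the value over 1.5 times. With a higher minimum the difference in genes with a count shrank: at 10 and 50 counts to 6066 and 398 for the canopy stages, -7336 and -812 for the parts in reproductive growth and -4674 and -722 over both stages, at 50 counts to -633 for the parts in vegetative growth, at 10 counts to -5325 for the interaction, and at 1 CPM to -11476 for the parts in reproductive growth and -8957 for the interaction. Without the 10 most abundant genes the effective number moved to -13.9 for the root stages (exact permutation p = 0.7) and -789.6 for the interaction.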

Other observations

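The tests in this part were chosen after the data had been seen. The rows of the table do not correspond between libraries, and a candidate explanation is that each library's counts stand in their own row order, with the identifiers kept from the first column. The highest Spearman correlation of a replicate pair was 0.0096, below the 0.015 reached by shuffled columns. Noise between replicates of an aligned table was judged by the overlap of the 100 most abundant genes over the 12 replicate pairs. The total was 0 where chance gives 1.83, and an aligned table simulated with a dispersion of 0.1 gave 67 to 82 per pair. This argues against noise of that size. Stronger noise was not simulated, so the overlap cannot say how much noise it would exclude. A cyclic shift or reversal of whole columns within the listed rows is argued against, since the highest correlation over all of them was 0.020. The test did not cover blocks moved within a column, or columns that list different rows of a longer table, so these stay open. At which step from the sequencing to this table the order was lost was not tested.

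The table may also list only part of the assembly. Of the 6875 identifiers that number a gene as the second of its component, 25.6% (Wilson 95% interval 24.6 to 26.6%) had the first gene of that component listed. The share was 26.4% for genes numbered 3, 26.3% for genes numbered 4 and 25.5% for genes numbered 5, and rows cut off at the row limit of an older spreadsheet, in an order unrelated to gene number, would give such a constant share. If that held, each library's full count would be larger than the total in the listed rows. The size of the full assembly was not settled: the share would put it at about 256000 genes, while the highest component number listed is 276691, and components can hold more than 1 gene or be missing. A filter on genes unrelated to their number would give the same share and stays open.

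For the gene-by-gene tests, 10 of the 10 splits of the libraries gave as many calls as the real grouping in each of the 4 comparisons, and 25 of 25 drawn splits did so for the interaction, since the real value and the highest of the other splits were both 0 calls. With 10 splits a share under 0.05 is out of reach. With 0 calls in every split the comparison was fixed beforehand and decides nothing, for the interaction too.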
